A study of Mus musculus with 9 samples.

How the data were processed

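RNA was sequenced from whole gonads of female mouse fetuses at 6 stages, given in days post coitum (dpc), and from 2 pools of adult tissue RNA. Per the labels, the gonads came from a C57/BL6xDBA/2 background, and the RNA of each stage was extracted from a pool of at least 34 ovaries. The stage of 11.5 dpc has 2 libraries and the stages of 12.5, 14.5, 16.5, 18.5 and 20.5 dpc have 1 library each. The somatic pool combines purchased RNA of 17 tissues of C57BL/6J adults, among them liver, brain, skeletal muscle, pancreas, skin and placenta. The other pool adds testis RNA to somatic tissue RNA, in a proportion not given in the sources used here. Libraries were directional total RNA libraries, per the labels' protocols.

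The deposited values are TPM, transcript abundances scaled to a fixed sum per library, which the authors obtained with kallisto 0.43.1 after bcl2fastq 1.8.2 on the mouse build mm10, per the submitters' processing notes. kallisto assigns reads to transcripts without alignment to the genome and divides reads that fit several transcripts by an estimate, so values of near-identical gene copies are uncertain. The table holds 49665 Ensembl genes, and the step from transcripts to genes is not given in the sources used here. Each column sums to 1000000, so TPM is a share of each library and a gene that takes a large share lowers all others. Read depth is not kept in TPM, so it is unknown, and no counting interval or detection floor was computed. Of the gene identifiers, 49406 were matched to GENCODE M21, an annotation of GRCm38 (the assembly called mm10), which gave coordinates and gene types. All 9 columns were mapped to samples by title.

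Values were analysed as log2(TPM + 1), a scale that understates changes of low genes. The trend over the 7 gonad libraries was tested with limma 3.58.1 in R 4.3.3. A line on the day was fitted for genes with a mean of at least 1 TPM, with a moderated two-sided test, a variance prior that follows expression, and Benjamini-Hochberg adjustment at 0.05. Slopes are printed as the fitted change over the 9 days from 11.5 to 20.5 dpc, with its standard error over 7 libraries. Whether the 2 libraries of 11.5 dpc came from separate collections is not given in the sources used here, so the p-values measure the spread of these libraries around the line. Because all stages but the first have 1 library, comparisons between stages and between pools used a rule of size without p-values. A gene counted as higher or lower when log2(TPM + 1) differed by at least 2, which is 4-fold on that scale and needs a level of at least 3 TPM. Against the somatic pool, every ovary library had to pass for the total counts. Members of gene lists were counted there by the mean of the 7 ovary libraries. In every comparison by size, list members needed a mean of at least 1 TPM over the libraries compared. A member could pass this filter through the higher side alone, and members low on both sides were left out. These steps used Python 3.11.15 with pandas 2.3.3 and NumPy 2.4.6.

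Before the data were examined, 23 gene lists with 394 entries were fixed, of which 383 were found by symbol. The lists share some genes, such as Kit, Sall4 and Stra8, and some genes were entered under both an older and a newer symbol. Lists with at least 3 tested members were tested for trend with camera of limma at a preset inter-gene correlation of 0.01, and again with an estimated correlation. In comparisons by size, a list's median was placed among the medians of 10000 random lists of as many genes matched on expression in 50 bins, which describes these libraries only. Genes were named by a rule fixed beforehand. It took the 8 steepest called genes per direction, the 8 largest differences per direction of each comparison by size, the 12 genes with the largest smaller difference for the overlap, 4 members per list, and 25 fixed genes. Gene models without a standard symbol were passed over except as list members. A few further list members are named as examples.

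The trend test was tested on simulated data with the real means and 15250 genes. It recovered 10.4% of genes changed 2-fold over the course, 60% at 4-fold, 90% at 8-fold and 92% at 16-fold, and called 6 of 15052 unchanged genes. The noise was independent between genes, with spreads shuffled over genes and capped. These rates therefore leave out differences that many genes of a real library share, and are not the false-call rate of the real data. The rule of size, simulated for 1 library against 1 with 14929 genes, called 27% of genes changed 4-fold and 89% of those changed 8-fold, and 2 of 14729 unchanged genes. That simulation gave all genes 1 spread and independent noise. The 2 real libraries of 11.5 dpc differed by the rule in 142 genes, so the simulated count understates calls between real libraries of 1 stage. The alternatives were pseudocounts of 0.1 and 5 TPM, a filter at 5 TPM or none, median-of-ratios scaling, the rank of the stage, a squared term of the day, a variance prior without trend, and each gonad library left out in turn. No paired analysis was possible because every group but 11.5 dpc has 1 library, and the replicate number given here only counts libraries within a group and links none across groups.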

Results

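Transcript levels were measured in 7 libraries of whole female mouse gonads from 11.5 to 20.5 dpc and in 2 pools of adult tissue RNA. The question, from the study's title, is how the gonad transcriptome compares with that of somatic tissues. The gonad libraries held between 14750 and 15636 genes at 1 TPM or more, the somatic pool 18329 and the testis-containing pool 20584. Fragments of ribosomal RNA took 3.40% of TPM in replicate 1 of 11.5 dpc and 0.369% to 1.53% in the other gonad libraries. Xist, the RNA that silences an X chromosome in females, lay between 71.8 and 137 TPM in the gonads, and the Y-linked Ddx3y at 0.356 TPM or less. In the somatic pool Ddx3y was at 7.06 TPM and Xist at 70.6 TPM. Except at 11.5 dpc, no value has a replicate.

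Across the 6 stages, oocyte genes rose most steeply. Figla, a transcription factor of oocytes (chromosome 6, 86016171 to 86020996, mm10), was at 0.195 and 0.407 TPM at 11.5 dpc and at 280.8 TPM at 20.5 dpc. Its fitted change was 8.86 ± 0.96 (SE, 7 libraries, log2 scale), with a limma adjusted p of 0.00115. Nlrp5, a maternal-effect gene of the egg, rose by 8.85 ± 1.24, and the oocyte transcription factors Nobox, Lhx8 and Sohlh1 rose by 7.74 ± 0.79, 7.34 ± 0.75 and 6.72 ± 0.72. The oocyte growth factor Gdf9 rose by 4.83 ± 0.63 and the egg-coat gene Zp3 by 5.98 ± 1.16. The Zp3 call was lost without the 20.5 dpc library (adjusted p = 0.0616). Of 23 tested members of the oocyte and folliculogenesis list, 20 rose and 0 fell, the same counts as when adjusted over the list alone. Genes of the piRNA pathway, which restrains transposons in germ cells, rose too: 12 of 18 rose and 0 fell, with 14 rising when adjusted over the list alone. Tdrd9 rose by 7.36 ± 0.75, Gtsf1 by 7.31 ± 0.52, Tdrd1 by 6.57 ± 0.40 and Mov10l1 by 4.84 ± 0.80. The cyclin gene Ccno, outside the lists, rose by 7.55 ± 0.96.

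Genes of pluripotency and of primordial germ cells fell. Utf1, a chromatin factor of pluripotent cells, was at 72.5 and 144 TPM at 11.5 dpc, at 170 TPM at 12.5 dpc and at 0.246 TPM at 20.5 dpc, a fitted change of -7.76 with a limma adjusted p of 0.00209. Sox2, Tfap2c and Nanog, transcription factors of early germ cells, changed by -6.01 ± 0.91, -4.83 ± 0.86 and -4.82 ± 0.77. Of 19 tested members of this list, 11 fell and 0 rose, with 14 falling when adjusted over the list alone. Pou5f1 did not pass (fitted change -2.73, limma adjusted p = 0.209). It went from 249 TPM at 12.5 dpc to 2.73 TPM at 16.5 dpc and stood at 60.7 TPM at 20.5 dpc. The X-linked homeobox genes Rhox9 and Rhox6 fell, with changes of -7.03 ± 0.93 and -6.13 ± 0.76. Of the 10 tested spermatogonial list members 2 rose and 4 fell, among them Dmrtb1 (3.80 ± 0.61) and Etv5 (-3.35 ± 0.61).

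Of 19 genes of the chromosome axis and synaptonemal complex, the scaffold that pairs chromosomes in meiosis, 6 rose over the course, 0 fell and 13 did not pass, with 7 rising when adjusted over the list alone. Sycp3 rose by 6.43 ± 1.44 and Sycp2l by 5.52 ± 1.02. In the list of meiotic double-strand break formation and recombination 8 of 29 rose and 1 fell, with 10 rising and 1 falling when adjusted over the list alone. Tex15 rose by 3.98 ± 0.69. Several fixed genes of meiosis did not pass the test for a line. Stra8, the retinoic acid target that starts meiosis, was at 0.0518 and 0.0732 TPM at 11.5 dpc, 12.8 TPM at 12.5 dpc, 208 TPM at 14.5 dpc and 0.671 TPM at 20.5 dpc (limma adjusted p = 0.884). The recombinase Dmc1 was at 58.6 TPM at 14.5 dpc and 1.87 TPM at 20.5 dpc (0.854). Spo11, which cuts DNA in meiosis, was at 26.1 TPM at 16.5 dpc (0.498), and Ankrd31 at 11.02 TPM at 16.5 dpc (0.266). Ccdc36 (also called Iho1) and Mei4 were at 20.4 and 3.37 TPM at 14.5 dpc (0.889 and 0.276), and Rec114 was at 37.4 TPM at 14.5 dpc and 34.9 TPM at 20.5 dpc (0.0508). Of 12 members of the meiotic entry list 0 rose and 3 fell, Dmrt1 (-4.81 ± 0.64), Msx1 (-2.93 ± 0.41) and Msx2 (-2.49 ± 0.52). Msx2 was not called without the 20.5 dpc library (adjusted p = 0.051). Ddx4 and Dazl, markers of germ cells, did not pass (limma adjusted p = 0.344 and 0.434). Ddx4 was at 9.22 and 30.7 TPM at 11.5 dpc, 92.5 TPM at 14.5 dpc and 42.8 TPM at 20.5 dpc. Dazl was at 12.1 and 37.9 TPM, 173 TPM and 64.9 TPM at these stages. Libraries of whole gonads do not separate a changed share of germ cells from changed expression within them, for these or other germ cell genes.

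**Figure D1:**
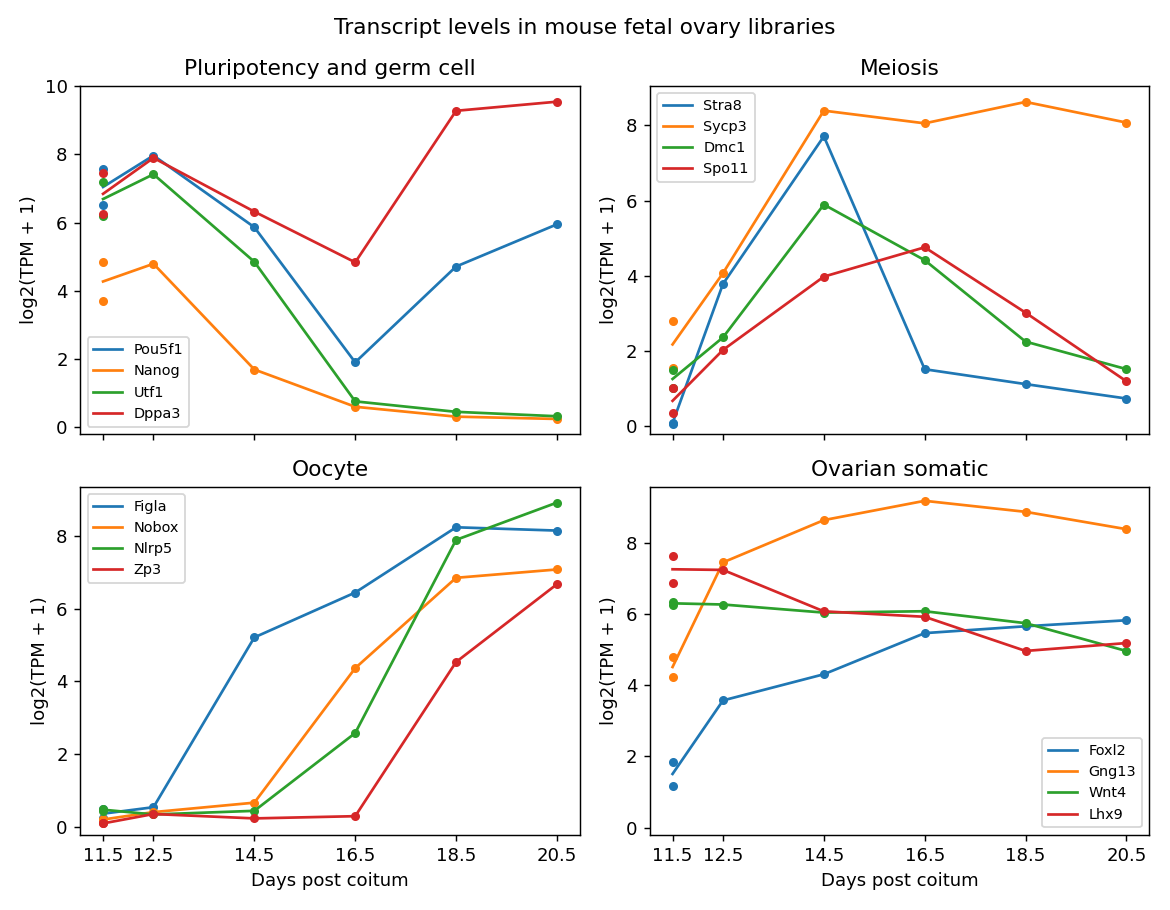
Level of 16 named genes as log2(TPM + 1) against days post coitum in 7 fetal ovary libraries, where points are libraries and lines join stage means. Nanog and Utf1 run down from 12.5 dpc, Stra8 and Dmc1 are highest at 14.5 dpc, Spo11 is highest at 16.5 dpc, and Figla, Nobox, Nlrp5 and Zp3 are near 0 at 11.5 dpc and above 6 at 20.5 dpc.

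Genes known from somatic cells of the gonad changed in both directions in these whole-gonad libraries, which do not separate cell types. Foxl2, a transcription factor of granulosa cells, rose by 4.33 ± 0.70 and the estrogen receptor gene Esr2 by 2.89 ± 0.35. Of 15 pregranulosa and ovarian somatic genes 7 rose and 2 fell, and Wnt4 was among those that fell (-1.10 ± 0.23, not called without the 20.5 dpc library, adjusted p = 0.078). In the gonad primordium list 6 of 12 fell and 0 rose, with 7 falling when adjusted over the list alone, and Lhx9 changed by -2.42 ± 0.34. In the list named for Sertoli cells and testis determination 6 of 11 rose and 0 fell, with 8 rising when adjusted over the list alone. Those were Ptgds (3.88 ± 0.26), Aard (2.73 ± 0.46), Defb19 (2.50 ± 0.41), Amh (1.68 ± 0.27), Fgf9 (1.56 ± 0.44) and Sox8 (1.07 ± 0.28), while Sox9 did not pass (limma adjusted p = 0.631). Cell cycle genes, which any dividing cell uses, fell in 12 of 18 cases and rose in 0, with 13 falling when adjusted over the list alone, such as Top2a (-2.60 ± 0.34) and Rrm2 (-2.23 ± 0.31). Of 12 interstitial and steroidogenic genes 1 rose, Hsd3b1 (5.06 ± 0.69), and 5 fell. In the smooth muscle and extracellular matrix list 6 of 14 rose and 2 fell, with 9 rising and 3 falling when adjusted over the list alone, and with Col6a1 at 2.76 ± 0.49 and Fn1 at -1.52 ± 0.25.

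Among markers of blood, vessel, duct and other tissue cells, some single genes changed, and of their lists camera called the endothelial one alone (adjusted p = 0.000317, and adjusted p = 0.556 with an estimated correlation). The embryonic globin genes Hbb-y, Hba-x and Hbb-bh1 fell most steeply of all genes named, by -12.89 ± 1.21, -11.94 ± 1.06 and -10.04 ± 1.63. Hbb-y was at 7950 and 4821 TPM at 11.5 dpc and 1.89 TPM at 20.5 dpc. The adult Hbb-bs rose (3.86 ± 1.08), a call lost without either 11.5 dpc library, the 12.5 or the 18.5 dpc library (highest adjusted p = 0.0971). In the erythroid list 1 of 12 rose and 3 fell. Of 13 endothelial genes 5 fell and 0 rose, with Plvap at -3.39 ± 0.33. Of 10 mesonephros and duct epithelium genes 1 rose and 4 fell, with Lhx1 at -2.33 ± 0.49 and Cdh6 at -1.84 ± 0.37. Of 11 macrophage genes 1 rose, Lyz2 (1.95 ± 0.52, not called without the 20.5 dpc library, adjusted p = 0.136), and 0 fell, and 0 rose when adjusted over the list alone. The adult somatic tissue list had 4 rising and 6 falling of 16, among them the pancreatic Cpa1 (-5.66 ± 0.50) and the villus gene Vil1 (5.02 ± 0.88). Sprr2d and Sprr2a2, epithelial envelope genes with near-identical copies, changed by -6.49 ± 1.32 and -6.07 ± 1.13. Of 11 immediate early and heat shock genes 2 rose and 0 fell, with Egr1 at 3.77 ± 0.84, and 1 rose when adjusted over the list alone. None of 7 DNA methylation genes and none of 12 mitochondrial genes passed with limma, and 1 rose and 1 fell of 8 spermatid genes, with 4 rising and 1 falling when adjusted over the list alone. For lists without such a count, those adjusted over the list alone were the same.

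Of 15612 genes tested with limma, 2818 rose and 1436 fell, and 11358 did not pass. Without the 18.5 dpc library 1480 rose and 619 fell, and without replicate 2 of 11.5 dpc 840 fell. Camera called 9 lists, with adjusted p of 1.07e-09 for oocyte, 3.43e-08 for pluripotency, 1.33e-07 for cell cycle, 1.3e-06 for piRNA, 0.000146 for gonad primordium, 0.000317 for endothelial, 0.0145 for axis, 0.0263 for Sertoli and 0.0424 for recombination genes. No call held with an estimated correlation, where the oocyte, piRNA, cell cycle, gonad primordium and Sertoli lists had adjusted p = 0.521 with an estimated correlation, the pluripotency list 0.528, the endothelial list 0.556, and the axis and recombination lists 0.659. The axis list was not called without replicate 1 or 2 of 11.5 dpc (adjusted p = 0.113 and 0.067). The recombination list was not called without those (0.166 and 0.168), without 12.5 dpc (0.0533), without 16.5 dpc (0.0559) or with a pseudocount of 5 TPM (0.0795). The other lists had camera adjusted p of 0.0682 (mesonephros), 0.108 (immediate early and mitochondrial), 0.114 (adult somatic), 0.135 (pregranulosa and erythroid), 0.143 (interstitial), 0.169 (DNA methylation), 0.199 (smooth muscle), 0.303 (macrophage and spermatogonial), 0.304 (meiotic entry) and 0.386 (spermatid). In the meiotic entry list the median change was 0.79 and the mean -0.19, and in the erythroid list they were 0.21 and -2.40. Of 79 called genes among those named by the rule, 49 were called with each library left out in turn.

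At 14.5 dpc, all 18 axis genes with a mean of at least 1 TPM over the libraries compared were higher than at 11.5 dpc. Most recombination genes were too. The axis gene Sycp2l missed that filter, at 0.059 and 0.103 TPM at 11.5 dpc and 0 TPM at 14.5 dpc. Stra8 (chromosome 6, 34920163 to 34939344) was higher at 14.5 dpc by 7.62 on the log2 scale, Sycp3 by 6.21 (5.58 without replicate 1 and 6.84 without replicate 2 of 11.5 dpc), Syce3 by 6.13, Tex12 by 5.43 and the cohesin gene Rad21l by 5.39. The 18 axis and synaptonemal complex genes had a median of 4.39, and 21 of 29 recombination genes were higher, with a median of 2.995. Both medians lay at percentile 100 of random lists matched on expression. Prdm9, which marks recombination sites, was higher by 4.90, Meiob by 4.71 and Dmc1 by 4.64. Of 12 meiotic entry genes 5 were higher, among them Gm4969 (5.32), now named Meiosin, and Meioc (5.06). In the piRNA list 7 of 15 were higher, with Mael at 4.64, and in the oocyte list 2 of 11 were, Figla (4.83) and Sohlh2 (2.14). Tex101 was higher by 6.85 and Dmrtc2 by 5.55. Of 14 pregranulosa genes 4 were higher, Gng13 (4.13), Irx3 (2.92), Foxl2 (2.81) and Lgr5 (2.49). The immediate early gene Fos was higher by 5.75, and 5 of 11 genes of its list were, with a median of 1.98.

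Lower at 14.5 dpc were the embryonic globins Hbb-bh1 (-7.66) and Hba-x (-4.87), and 2 of 20 pluripotency genes, Nanog (-2.58) and Esrrb (-2.27), with a list median of -1.18 at percentile 0. Sprr2d (-5.83), Sprr2a2 (-5.02), the lipase gene Pnliprp2 (-5.10) and Tgm3 (-4.36) were lower too. Rn7s2 (-5.95) and H3f3c (-4.98) were also among the largest, and both have near-identical copies in the genome. Without replicate 1 of 11.5 dpc the differences of Rn7s2 and H3f3c were -4.62 and -6.46, and without replicate 2 they were -7.28 and -3.49. The steroid enzyme gene Cyp11a1 (-4.25) and Cyp26b1 (-3.40), which degrades retinoic acid, were lower. Medians of the duct epithelium list (-1.09), the interstitial list (-0.98), the gonad primordium list (-0.85), the endothelial list (-0.75) and the cell cycle list (-0.69) were negative, with 0, 2, 0, 0 and 0 members lower by the rule. Between replicates 1 and 2 of 11.5 dpc these lists had medians of 1.58, 0.04, -0.52, 0.49 and -0.13, in that order. The duct epithelium median thus depends on which library of 11.5 dpc is used. In all, 339 genes were higher and 142 lower.

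The 2 libraries of 11.5 dpc differed by the same rule in 142 genes, 106 higher and 36 lower in replicate 1, with an SD of 0.59 over 14929 genes. Markers of duct epithelium were higher in replicate 1 by a median of 1.58, those of smooth muscle and matrix by 1.17 and of macrophages by 1.02. Pluripotency and piRNA genes had medians of -1.01 and -1.06 there, and axis genes -1.18. Without replicate 1, 344 genes were higher and 231 lower at 14.5 dpc.

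From 14.5 to 20.5 dpc, oocyte genes went up and many genes of meiosis down. Nlrp5 was higher at 20.5 dpc by 8.45, Padi6 by 7.38, the egg-coat genes Zp2 and Zp3 by 6.92 and 6.42, Ccno by 6.97, Nlrp4f by 6.52 and Nobox by 6.40, and 22 of 23 oocyte genes were higher, with a median of 4.73 at percentile 100. Of 18 piRNA genes 6 were higher, with Tdrd1 at 4.34 and Tdrd9 at 4.01. Stra8 was lower by -6.97, Dmrtc2 by -4.74 and M1ap, a gene needed for spermatogenesis, by -5.05. Of 19 axis genes 9 were lower, with Majin at -4.01 and Hormad1 at -3.43, and 1 was higher, Sycp2l (5.56). Of 29 recombination genes 12 were lower and 0 higher, with Dmc1 at -4.37 and Spo11 at -2.78. Of 12 meiotic entry genes 6 were lower. The germ cell genes Rhox9 (-5.71), Rhox5 (-4.97) and Rhox6 (-4.77) were lower, as were 4 of 18 pluripotency genes such as Sox2 (-3.90), while Dppa3, a maternal factor, was higher (3.22). Hbb-y (-7.65) and Hba-x (-5.72) were lower, and Rn7s2 was higher by 6.06 with levels that vary without order between stages. The immediate early list had a median of -1.16 with 1 of 11 lower, Atf3 (-2.22). In all, 587 genes were higher and 180 lower, with no replicate of either stage. In TPM the middle gene lies 0.17 higher at 20.5 dpc, and median-of-ratios scaling, which removes that offset, gave 533 and 206.

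Adding testis RNA to the somatic tissue brought in genes of sperm formation. Prm2, a protamine that packs sperm DNA (chromosome 16, 10791380 to 10796134), went from 2.58 TPM in the somatic pool to 1810 TPM in the testis-containing pool, a difference of 8.98. Tnp1 and Tnp2, transition proteins of spermatids, were higher by 8.47 and 7.35, Meig1 by 7.82, Fabp9 by 7.72, Spata4 by 7.39, Tcp11 by 7.30 and Smcp by 7.19. Prm1 was at 9.17 and 1386 TPM. All 25 spermatid genes were higher, with a median of 5.50 at percentile 100. Of 18 piRNA genes 14 were higher, with Mael at 6.59, Gtsf1 at 5.72 and Ddx4 at 5.07. Of 16 axis genes 10 were higher, led by Syce1 (5.38) and Hormad1 (4.28), and 6 of 23 recombination genes were, led by Cntd1 (3.11). Few markers of testis somatic cells passed. Of 12 Sertoli list genes 3 were higher, Defb19 (5.86), Cst9 (5.44) and Aard (2.87), with a list median of 0.20, and of 10 interstitial genes 1 was, Insl3 of Leydig cells (5.25). Of 14 pregranulosa list genes 1 was higher, Amhr2 (3.19). Of 8 spermatogonial genes 1 was higher, Dmrtb1 (6.19), and of 11 meiotic entry genes 3 were, Dazl (3.52), Meioc (3.14) and Rbm46 (2.10).

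None of 45 adult somatic tissue genes passed by size between the pools, and their median was -0.24, at percentile 0. The Y-linked and Xist list had a median of 0.16 over 5 genes with none passing. In all, 1621 genes were higher in the testis-containing pool and 17 were lower. The lower ones included Defa5 (-4.81), Hist2h2aa2 (-4.53), Igkv13-84 (-4.31) and Rn7s2 (-2.53), which belong to families of near-identical copies. Each pool is 1 library, so the difference has no replicate check.

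Compared with the somatic pool, the gonads stood out by germ cell genes and by transcription factors of the gonad. The mean of the 7 ovary libraries exceeded the pool by 7.29 for Dppa3, 6.25 for Dppa5a and 6.09 for Fkbp6, a gene needed for chromosome pairing. Nr5a1 and Lhx9, factors that form the gonad, were higher by 5.93 and 5.90, Wnt6 by 6.03 and Kctd14 by 6.70. The antisense gene Sardhos (5.90) was listed at 0 in both pools. Over those means, 10 of 12 gonad primordium genes were higher, with Wt1 at 5.10 and Gata4 at 4.80, and 10 of 15 pregranulosa genes, with Amhr2 at 5.71. The axis list had 16 of 19 higher, the piRNA list 12 of 18, the pluripotency list 11 of 19 and the recombination list 13 of 28. Cell cycle genes were higher in 9 of 18 cases, with a median of 1.99.

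By the mean of the 7 ovary libraries, all 44 adult somatic tissue genes that passed the filter were lower in the gonads. Their median was -6.76. The muscle genes Ckm, Acta1 and Tnnc2 differed by -12.10, -11.88 and -11.78, the kidney gene Kap by -11.92, and the gland genes Mucl2 and Prol1 by -15.67 and -12.10. Scgb1b27 (-13.01) and Scgb2b27 (-11.84), like Kap, were listed at 0 in every gonad library. The ribosomal protein gene Rps12, at 802 and 512 TPM in the pools, was listed at 0 there too, so a listed 0 does not by itself show low expression, and these differences are not exact. Albumin (Alb) was at 9.05 TPM in replicate 1 of 11.5 dpc and at 1.20 TPM or less in the other gonad libraries. By the same mean, of 13 macrophage genes 9 were lower, with Lyz2 at -5.61, and of 14 smooth muscle and matrix genes 9 were lower, with Cnn1 at -5.54. Requiring every ovary library to pass left 279 genes higher and 2377 lower. In TPM the middle gene lies 0.53 higher in the gonads, and with median-of-ratios scaling, which removes that offset, 149 were higher. Age, strain and RNA source differ along with tissue between gonads and pools and cannot be separated here.

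A group of genes was higher both in the testis-containing pool than in the somatic pool and in the 14.5 and 16.5 dpc ovaries than at 11.5 dpc, and 9 axis and synaptonemal complex genes were among them. Tex101 differed by 5.34 between the pools and by 6.30 in the ovary, Mael by 6.59 and 4.76, Sycp3 by 4.17 and 6.05, Syce3 by 4.11 and 6.66, and Sycp2 by 4.15 and 4.36. Syce1 (5.38 and 3.97), Smc1b (3.91 and 4.70) and Hormad1 (4.28 and 3.69) followed, with Cst12 (5.15 and 5.01), Lypd4 (5.78 and 3.93), Adad1 (4.97 and 3.82) and Zfp541 (3.79 and 4.47). From the fixed lists, 7 piRNA genes, among them Ddx4 and Tdrd9, 5 recombination genes, among them Spo11, and the 2 entry genes Meioc and Dazl were higher in both. Aard and Defb19 of the Sertoli list and Dmrtb1 of the spermatogonial list were too. In all, 88 genes passed, and 72 of them lay under 1 TPM in the somatic pool. Independent lists would share 8.3 genes among 11503 genes, with 350 higher in the pool and 274 in the ovary. Those 11503 had log2(TPM + 1) of at least 2 in the testis-containing pool and over 14.5 and 16.5 dpc, with no limit on the lower sides. Among the 19045 genes with a mean of at least 1 TPM the figure was 30.3. Genes at low levels in the somatic pool and at 11.5 dpc can pass both more easily, so both figures may be too low. The 2 differences share no library.

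**Figure D2:**
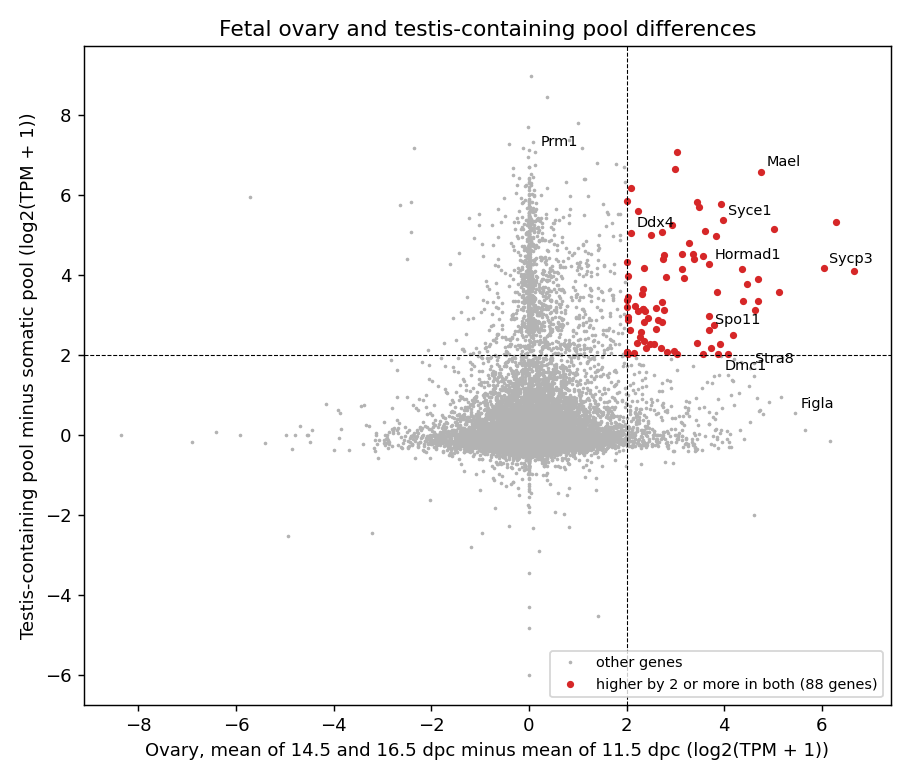
Difference between the 2 pools (testis-containing minus somatic, vertical axis) against the difference in the ovary (mean of 14.5 and 16.5 dpc minus mean of 11.5 dpc, horizontal axis), both in log2(TPM + 1), for 19045 genes. Points in the upper right beyond the dashed lines at 2 are the 88 genes higher in both, with Sycp3 and Mael among them, while Prm1 is high on the vertical axis alone.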

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

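The counts by size depend on the pseudocount, by construction, since it damps low genes. In the order 14.5 over 11.5 dpc (higher, lower), 20.5 over 14.5 dpc (higher, lower), testis-containing pool (higher, lower), higher in every ovary library, and higher in both, a pseudocount of 0.1 TPM gave 831, 455, 1192, 476, 2615, 81, 555 and 265 genes. With 5 TPM these were 151, 39, 219, 63, 667, 5, 114 and 19, and 1092 genes were lower in every ovary library. A filter at 5 TPM left 11 genes lower in the testis-containing pool, as fewer genes are tested, and median-of-ratios scaling left 149 genes higher in every ovary library, as it moves the middle gene. Dropping the filter tests nothing for these counts, since the rule itself needs 3 TPM. With a library left out, rising genes ranged from 1480 to 3033 and falling genes from 619 to 1619, lowest without 18.5 dpc, where the cause was not tested. Genes lower at 14.5 dpc numbered 231 without replicate 1 and 198 without replicate 2 of 11.5 dpc. The 9 list calls fell to 0 with an estimated correlation and ranged from 8 to 13 with a library left out. A pseudocount of 5 TPM left 8, without the recombination list (adjusted p = 0.0795), and no filter gave 11, adding the mesonephros (0.0274) and pregranulosa (0.0208) lists. Among the counts that were rerun, namely trend calls, list calls, totals by size and the overlap, all others stayed within 1.5 times. Counts of list members, of neighbouring stages and of the stage of highest level were not rerun. The squared term tests for any change over the days, with the direction taken from the line. It called 3471 rising and 1781 falling genes, of which 2572 and 1235 were among the main calls. Scaling by median ratios gave 2448 rising and 1884 falling genes, 56.5% rising against 66.2% in the main setting. No difference named by size reversed, and no trend of a named gene did where the gene was called in either setting. A change of sign in a gene called in neither setting was not counted. Of the trend values of named genes under the alternatives, 1492 kept the side of the threshold, 105 lost it and 46 gained it. Of the 60 log2 differences named by size, 57 moved with a pseudocount of 5 TPM and 47 with 0.1 TPM. A gene named in several comparisons counts in each. The printed differences therefore hold for a pseudocount of 1 TPM. Depth is unknown and limits low genes in a way that could not be measured.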

Other observations

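Of the tests below, that of germ cells as the only cause was chosen after the result was seen, and so was the choice of the larger of the placenta and pancreas gaps as the deciding value. The stages can also be told by where a gene was highest. Of 2095 genes whose stage levels span at least 4-fold, 821 (39.2%) were highest at 20.5 dpc, 345 at 16.5 dpc, 285 at 11.5 dpc, 235 at 14.5 dpc, 208 at 18.5 dpc and 201 at 12.5 dpc. Of 16 such pluripotency genes 15 were highest at 12.5 dpc. The level at 11.5 dpc was the mean of 2 libraries, and this list had a median of -1.01 in replicate 1 against replicate 2. Averaging in replicate 1 lowers the 11.5 dpc level of this list, and the count was not rerun without it. Of 19 axis genes 13 were highest at 14.5 dpc, as were 14 of 21 recombination genes, and 20 of 23 oocyte genes were highest at 20.5 dpc. Pou5f1 and Dppa3 were lowest at 16.5 dpc, at 2.73 and 27.5 TPM, and stood at 60.7 and 745 TPM at 20.5 dpc, while Nanog, Sox2 and Utf1 were at 0.246 TPM or less by then. Between neighbouring stages, 287 genes passed by size from 12.5 to 14.5 dpc, 181 from 14.5 to 16.5 dpc and 195 from 16.5 to 18.5 dpc. The 2 libraries of 11.5 dpc differed in 142 genes by the same rule, more than the 82 from 18.5 to 20.5 dpc. From 11.5 to 12.5 dpc 89 genes passed, but that step used the mean of the 2 libraries of 11.5 dpc. A mean can damp differences between single libraries, so the 89 and the 142 are not compared like for like.

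A few genes known from pancreas and skin, grouped after the values were seen and not tested together, were measured in the youngest gonads. The pancreas genes Prss2 and Amy2a1 were listed at 0 in all 7 gonad libraries, but a listed 0 does not by itself show low expression. Cpa1 was at 56.1 and 80.3 TPM in the 2 libraries of 11.5 dpc, Pnliprp2 at 41.8 and 63.4 TPM, Lor at 52.9 and 83.0 TPM and Sprr2d at 53.55 and 89.2 TPM. All of these were lower in replicate 1, as were germ cell genes, and at 20.5 dpc they were at 0.721, 0.913, 2.14 and 0.0714 TPM. Of the globin genes, Hbb-y went from 579 TPM at 14.5 dpc to 8.20 TPM at 16.5 dpc, where Hbb-bs was at 9163 TPM. The ribosomal protein gene Rps12 and 31 other genes at 100 TPM or more in both pools were listed at 0 in all 7 gonad libraries.

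The 2 libraries of 11.5 dpc differed in 142 genes. The largest differences toward replicate 1 were in Afp (115 against 0.112 TPM), Apoa1 (33.1 against 0.405 TPM), the noncoding Rmrp (442 against 18.4 TPM) and Cdh16 of the duct epithelium (24.9 against 0.314 TPM), with Rn7sk and the liver-type genes Ttr, Alb and Rbp4 also among the first 10. A second list of 14 germ cell genes had a negative difference in replicate 1 in all 14 cases, with a median of -0.8766. That goes with a lower share of germ cells there. It adds little to the first germ cell lists, which were already lower in replicate 1, and its genes are not independent cases. As the only cause, a lower share of germ cells is argued against by the gonad primordium list. Its median was -0.522, while that of macrophages was 1.02. Duct epithelium may be part of the difference, though its second list had a median of only 0.5955 with 7 of 11 above 0, between the bounds of 0.5 and 1 set beforehand. Replicate 1 alone has a title prefix (AT) that differs from the prefix (KA) of replicate 2 and all later stages, and its meaning is not given in the sources used here, so collection, dissection or batch stays open and untested.

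At 14.5 dpc 5 of 11 immediate early genes were higher than at 11.5 dpc by the rule of size, but only 2 of 11 rose over the course. Camera did not call the list (adjusted p = 0.108, but 0.0336 without the 14.5 dpc library and 0.00562 without the 20.5 dpc library). These values used the preset correlation, and with an estimated correlation and all gonad libraries camera gave an adjusted p of 0.659. Fos was at 2.15 TPM or less until 12.5 dpc, 112 and 99.9 TPM at 14.5 and 16.5 dpc, and 20.7 and 28.5 TPM later. A stress or handling response in the later libraries could account for it. In a second list of 13 such genes, the mean from 14.5 dpc on minus that before was above 0 for 12, none of them by as much as 2, and the median was 0.9646, under the bound of 1 set beforehand. Every one of these libraries is also of a later stage, so handling and stage cannot be told apart.

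Genes of adult tissues had a median difference of -0.24 between the testis-containing and the somatic pool, and dilution of an identical somatic mix by testis RNA could lower them alike. Second lists of skeletal muscle, liver and pancreas genes had medians of -0.26, -0.23 and -0.37, but placenta genes had a difference above 0 in all 14 cases, with a median of 0.16. The gap of 0.4239 between placenta and muscle exceeded the spread of both lists and argues against the same mix in both pools. The quartile ranges of pancreas and muscle did not overlap either, but their gap of -0.1025 was within the bound of 0.2 set beforehand, so alone it would leave the question open. A different share of placenta RNA in the mix is an untested hypothesis.

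For the number of genes with a trend, the days were also assigned to the 7 libraries in 100 orders, the real one included. The real order gave 4254 called genes and the highest of the others 2252, so 1 of 100 orders gave as many and a chance order of the libraries is argued against as the cause.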
